A study of Mus musculus with 2 samples.

How the data were processed

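Mouse B16F10 melanoma cells grown in wild-type lungs, perforin-deficient lungs and perforin-deficient bones (knees) were measured in 1 pooled single-cell run with 2 libraries, polyadenylated RNA and hashtag oligonucleotides. Per the labels, lung tumours were digested for 20 min and crushed knees for 30 min, both at 37 °C, so digestion and site went together, and GFP-positive CD45-negative DAPI-negative cells were sorted. The sources were then marked with 3 TotalSeq-B hashtags, pooled and run on the 10x 3' v3 chemistry, at no fewer than 50000 reads per cell for RNA and 5000 for hashtags. The number of mice behind each source is not given in the sources used here.

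The values used are UMI counts as the authors deposited them, 1 matrix of genes by barcodes and 1 of 3 hashtags by barcodes. The submitters' processing notes name Cell Ranger 6.1.2, Seurat 4.3.0 and the mm10 build, while the file header names Cell Ranger 6.0.0. Both matrices hold called barcodes only. The RNA matrix had 15961 barcodes and the hashtag matrix 6208, with 11757 (73.7%) in the RNA matrix alone and 2004 in the hashtag matrix alone. The smallest hashtag total was 503 counts, so barcodes with fewer were not listed. Barcodes not listed in the hashtag matrix were left out of every comparison. A cell metadata table and an annotated object that the labels mention were not used here, so groups, clusters and names were rebuilt and may differ from those of the submitters.

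Hashtags were called with HTODemux of Seurat 5.3.0 in R 4.3.3 (centred log ratio, positive quantile 0.99), and doublets of 2 hashtags and negatives were removed. Doublets within 1 hashtag are not seen this way. Scrublet, run through scanpy 1.11.5, marked 3 of 3037 cells (0.0988%). It was run after the 8.56% of hashtag doublets had been removed, so the 2 rates are not comparable. How many doublets within 1 hashtag it missed is not known, and it was used as an alternative only. Cells needed at least 1000 genes and at most 15% mitochondrial counts. They were clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9) on 30 principal components of 2000 variable genes with 15 neighbours at resolution 0.5. The 4 clusters were led by Prc1, Top2a and Ube2c (cluster 0), Enho, Nrp2 and S100b (cluster 1), Lgals7, Kcnj13 and Spp1 (cluster 2), and Cck, Arfgef3 and Hgsnat (cluster 3). Clusters were named from 17 marker lists fixed before the data were examined. A cluster took the name of another type if at least 3 of its markers were among the 25 leading genes, and was called melanoma-like otherwise if at least 3 melanoma markers were each detected in at least 25% of its cells. Clusters of small droplets with no marker among their first 10 leading genes stayed unnamed. These naming thresholds were set after seeing the data. All 4 clusters carried the melanoma markers, and values were compared over all of them.

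Counts were summed over the cells of each group and divided by the group's total, to CPM. Ratios of CPM have exact conditional binomial intervals, levels have exact Poisson intervals and shares have exact Clopper-Pearson intervals, all at 95%. They cover counting error only, and a count of 0 is given with a floor of 3 UMIs. Log2 ratios had 1 CPM added to each side, which shrinks the ratios of low genes. Of 27 gene lists fixed before the data were examined (4 primary, 23 secondary, 604 entries), members with a mean of at least 10 CPM over the 2 groups entered the median. Its interval comes from 1000 Poisson redraws of the counts, and its percentile from 10000 random lists of the same size matched in 20 bins of mean expression. The percentile describes these libraries and is not a test. The median over all genes was 0.00 in the lung comparison and -0.03 in the bone comparison on the log2 scale, and no scaling moved it by 0.1.

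The rule for named genes was fixed before the data were examined. It takes, per comparison, up to 12 genes on each side with the most extreme log2 ratio among those with a mean of at least 20 CPM, at least 50 UMIs and an interval wholly beyond 1.5-fold, without mitochondrial, ribosomal protein and unnamed genes. It adds 4 abundant and 4 extreme members of each primary list, 2 and 2 of each other list described, Prf1, and 2 members of each marker list. A gene is called higher or lower at 1.5-fold or more with an interval that leaves out 1. Which secondary lists are described by their members was decided after their values were seen. All genes are named as the files pair symbols with identifiers.

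The step was tested on simulated counts drawn from the real totals, with 200 genes changed. Counts were Poisson draws from 1 shared profile, without variation between cells or animals, so the rates hold for counting error only. A list of 20 unchanged genes lay at percentile 52.65 in the lung comparison and 96.63 in the bone comparison. For the lung comparison (5759 genes) all 50 genes at each of 2, 0.5, 4 and 0.25-fold were called, and 11 of 5559 unchanged genes (0.198%). For the bone comparison (5721 genes) 50 of 50 were called at 2, 4 and 0.25-fold and 49 of 50 at 0.5-fold, and 62 of 5521 unchanged genes (1.12%).

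The alternatives fixed beforehand were 2 other hashtag callers (MULTIseqDemux, and a margin rule asking for 75% of the hashtag counts), a looser filter (200 genes, 25% mitochondrial) and a stricter one (2000 genes, 10%), Scrublet calls removed, cluster resolution 1, and all hashtag singlets. For the values they were TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), a total without mitochondrial and ribosomal protein genes, the mean of per-cell CPM, cells thinned to 5000 UMIs, no low-value filter or one of 50 CPM, and pseudocounts of 0.1 and 10 CPM. Added after seeing the data were cells thinned to 1500 UMIs, removal of cells with 2 or more UMIs, or with any, over 8 epithelial and myeloid genes, cells that 3 callers put in the same group, removal of cells with 5 or more Cck UMIs, clusters 0 and 2 alone, and removal of the top cell per gene. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.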

Results

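Melanoma cells of the mouse line B16F10 were profiled after they had been recovered from 3 sites: the lungs of wild-type mice, the lungs of Prf1-/- mice and the bones (knees) of Prf1-/- mice. Prf1 encodes perforin, the pore-forming protein of cytotoxic lymphocytes, and the series is about mechanical and immune control of where metastases form. Viable GFP-positive CD45-negative cells were sorted, each source was marked with 1 of 3 hashtag antibodies, and the pool was run once on a droplet platform, which gave 1 RNA library and 1 hashtag library. Each condition is therefore 1 hashtag group with no replicate, no test was made, and every comparison describes these 3 groups. Intervals are 95% intervals for counting error only and hold no spread between animals or between cells, so they are too narrow for genes whose UMIs lie in few cells.

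The RNA matrix held 15961 barcodes with 35150895 unique molecular identifiers (UMIs) over 32285 genes. Of these barcodes, 11757 (73.7%) were not listed in the hashtag matrix. Of the rest, hashtag calling placed 1559 (37.1%) in WT lung, 1789 (42.6%) in Prf1-/- lung and 472 (11.2%) in Prf1-/- bone, and 360 (8.56%) were doublets of 2 hashtags. The sources had been pooled in equal amounts per the labels, and the hashtag matrix held no barcode below 503 counts, so these numbers do not give the make-up of the pool. After the cell filter 1239, 1390 and 408 cells remained, with totals of 3856008, 4166822 and 1366785 UMIs and medians of 2891, 2774 and 3068.5 UMIs per cell.

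All of the filtered cells fell in clusters that carried melanoma markers, a share of 100% in each group. Clusters were named as wholes, so single cells of other types within them would not be seen. The summed melanoma markers, such as the pigment cell genes Pmel, Dct and Mlana, stood at 14737 UMIs per 1000000 (CPM) in WT lung, 14974 in Prf1-/- lung and 11603 in Prf1-/- bone. Most lung cells lay in clusters 1 and 2 and most bone cells in clusters 0 and 2, of which cluster 0 was led by proliferation genes. Prf1 (ENSMUSG00000037202) itself had 0 UMIs in every group, under a floor of 3 UMIs that equals 0.778, 0.720 and 2.19 CPM. A melanoma cell is not a source of perforin in any of these mice, so this zero does not check the genotypes.

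Markers of other cell types were low. Summed CPM in WT lung, Prf1-/- lung and Prf1-/- bone were 0.519, 0 and 0 for T and NK cells, 3.89, 2.64 and 3.66 for B and plasma cells, and 20.0, 9.84 and 19.0 for monocytes, macrophages and dendritic cells. Neutrophil markers stood at 0.519, 0.960 and 63.7 CPM, and in bone all 30 UMIs of S100a8 came from 1 cell. Alveolar and airway epithelial markers stood at 124, 15.1 and 19.0 CPM. The pan-immune markers stood at 273, 218 and 304 CPM, almost entirely from 1 member of the list. Erythroid markers stood at 1.04, 0.720 and 3.66 CPM, megakaryocyte and platelet markers at 0.259, 0.960 and 2.19, and mesothelial markers at 0.259, 0.480 and 0. Endothelial markers stood at 173, 142 and 170 CPM, with Eng, a TGF-beta co-receptor gene, at 70.3, 61.9 and 69.5. Fibroblast markers stood at 14.3, 11.5 and 18.3 CPM, pericyte and smooth muscle markers at 3.37, 2.16 and 1.46, and osteoblast and marrow stromal markers at 4.67, 5.76 and 3.66. Chondrocyte markers stood at 25.9, 23.04 and 19.0 CPM and osteoclast markers at 28.5, 23.5 and 14.6. Schwann cell markers stood at 227, 234 and 183 CPM, with most UMIs from Sox10 (130, 133 and 116 CPM), a gene that melanoma cells share.

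**Figure D1:**
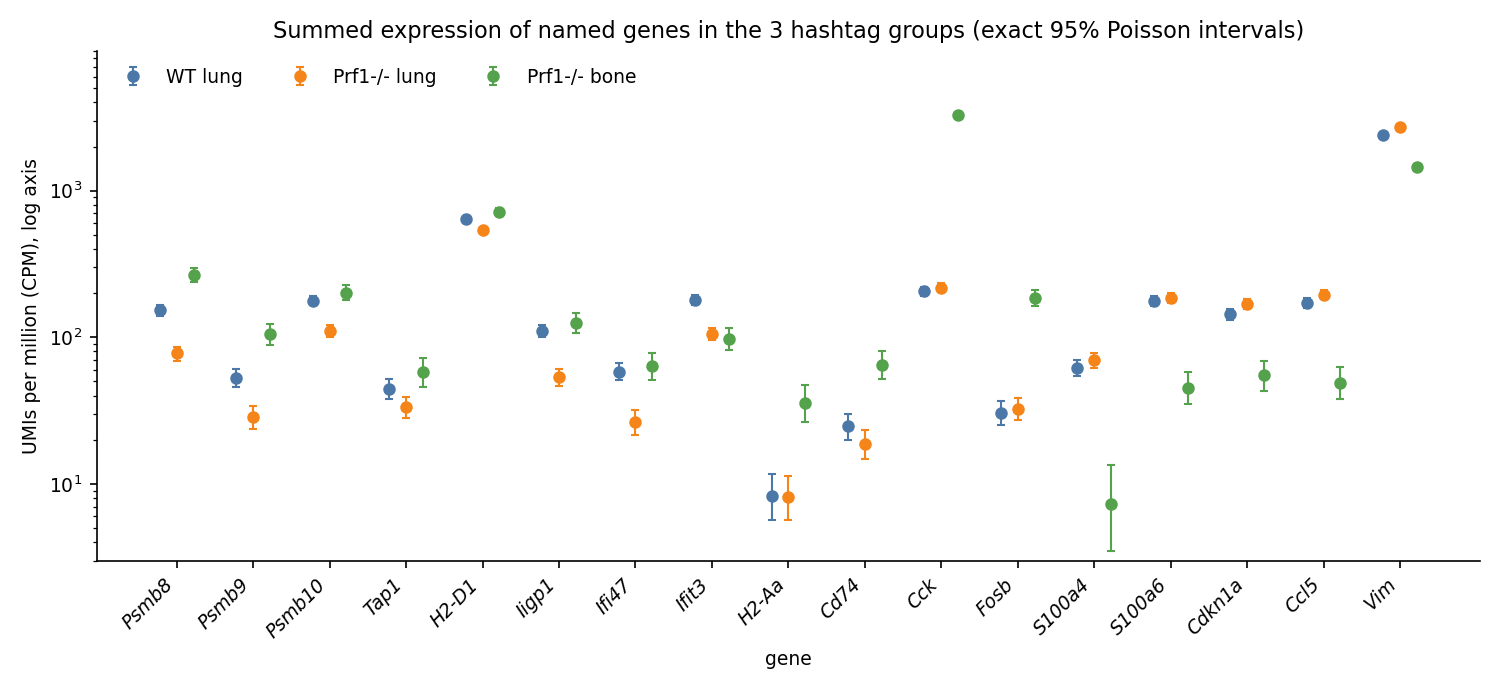
Summed expression of 17 named genes in WT lung, Prf1-/- lung and Prf1-/- bone, in CPM on a log axis, with exact 95% Poisson intervals as bars. Psmb8 stood at 152, 77.5 and 266 CPM and Cck at 207, 218 and 3270.4 CPM.

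The first comparison, Prf1-/- lung against WT lung, asks how melanoma cells in the lung differ when the host lacks perforin. Part of the interferon-induced and antigen-processing genes were lower in Prf1-/- lung: 11 of 27 measured interferon list members and 4 of 14 MHC class I list members. None of either list was higher. Psmb8, a catalytic subunit of the immunoproteasome, stood at 77.5 CPM against 152 in WT lung, a ratio of 0.509 (0.443 to 0.584). The immunity-related GTPase genes Iigp1 and Ifi47 had ratios of 0.487 (0.412 to 0.574) and 0.454 (0.358 to 0.573). Dnajb1, an Hsp40 co-chaperone gene, was higher in Prf1-/- lung, at 148 against 74.2 CPM and a ratio of 2.00 (1.73 to 2.31). It was the only gene that passed the naming rule in that direction.

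Of the 27 measured members of the interferon response list, 11 were lower by at least 1.5-fold with an interval that left out 1, and none was higher. The list's median log2 ratio was -0.51 (-0.63 to -0.44), at percentile 0 of 10000 random lists matched on expression, and all 27 members lay below 0. Gbp2, a guanylate-binding protein gene, had a ratio of 0.508 (0.407 to 0.633), Zbp1, a nucleic acid sensor gene, 0.508 (0.402 to 0.639) and Ifit3 0.588 (0.520 to 0.663). Oasl2 had a ratio of 0.427 (0.289 to 0.622) and Gbp3 of 0.485 (0.327 to 0.710). The members with the most UMIs differed less, with ratios of 0.777 for Ifitm3, 0.921 for Ifi27, 0.782 for Bst2 and 0.909 for the chemokine gene Cxcl10. Apol9a, an apolipoprotein L gene outside the list, had a ratio of 0.458 (0.371 to 0.563), and Lgals3, which encodes galectin-3, one of 0.478 (0.406 to 0.562).

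The MHC class I and antigen processing list had a median log2 ratio of -0.43 (-0.52 to -0.30), also at percentile 0. Of its 14 measured members 4 were lower and 10 passed in neither direction. The 4 were Psmb8, Psmb9 at 0.540 (0.427 to 0.680), Psmb10 at 0.619 (0.549 to 0.698) and the peptide transporter gene Tap2 at 0.463 (0.291 to 0.723). The class I light chain gene B2m had a ratio of 0.919 (0.880 to 0.960) and the heavy chain gene H2-D1 one of 0.837 (0.790 to 0.887). The chaperone genes Calr and Pdia3, which also serve protein folding in general, stood at ratios of 1.05 and 1.05. MHC class II had 2 measured members and a median of -0.18.

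The lists for mechanical response did not stand apart. None of 22 measured actin cytoskeleton and MRTF-SRF target genes differed by 1.5-fold, and their median was 0.00 at percentile 48.0, with Actb at 4023 CPM in WT lung and 4042 in Prf1-/- lung. The median of 9 YAP-TAZ targets was 0.06 at percentile 72.0, and 1 of them, Ccn1, was higher with a ratio of 1.52 (1.07 to 2.18). Integrins and focal adhesions had a median of 0.02, with 1 of 18 higher, the laminin receptor gene Itga6 at 1.95 (1.23 to 3.14), and medians were 0.02 for extracellular matrix and 0.05 for TGF-beta response.

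Other lists had smaller medians, some of them outside the range of the random lists. Proliferation lists lay slightly below 0, with medians of -0.08 for S phase (2 of 41 lower) and -0.06 for G2 and M phase. Medians were 0.11 for glycolysis (percentile 99.91, 1 of 16 higher, Aldoc at 1.58), 0.10 for hypoxia (2 of 10 higher, Kdm3a at 1.63 and Bnip3 at 1.61), 0.04 for nuclear oxidative phosphorylation genes (percentile 99.2), 0.00 for mitochondrially encoded genes and 0.01 for ribosomal proteins. The immediate-early and dissociation stress list, which contains Dnajb1, had a median of 0.12 at percentile 99.98, and cholesterol synthesis had 0.13 at percentile 99.915. Pigmentation genes had a median of 0.01 and the dedifferentiated melanoma list 0.14. Medians were -0.03 for ATF4 and amino acid stress, -0.02 for endoplasmic reticulum folding, 0.01 for NF-kB response, 0.14 for cytotoxic lymphocyte recognition, 0.01 for NRF2 and iron, 0.00 for p53 targets and 0.00 for lysosome. The bone metastasis list had 1 measured member, Spp1 (osteopontin), at a median of 0.40. The S phase, glycolysis, immediate-early and cholesterol medians reversed in some subsets of cells, with values given under the processing. The G2 and M phase median turned to 0.07 under the stricter filter.

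Alveolar epithelial transcripts went with the WT lung group, in the direction of the interferon genes: Sftpc, the surfactant protein C gene, stood at 98.3 CPM there and 10.8 in Prf1-/- lung. In WT lung 1 cell held 61.5% of the UMIs, and the ratio of 0.110 (0.0788 to 0.150) became 0.279 without the top cell of each group. Without the 5 WT lung and 1 Prf1-/- lung cells that held 2 or more UMIs over 8 epithelial and myeloid genes, the log2 ratio of Sftpc turned from -3.07 to 0.47, and without the cells that held any, which left 1190 and 1325, the interferon median was -0.52. In the 119 and 98 cells with at least 2000 genes, the ratios of Zbp1 and Ifit3 turned above 1 (log2 0.06 and 0.13) and that of Ccn1 below 1 (log2 -0.017), the log2 ratio of Iigp1 moved to -0.070, and the cytotoxic lymphocyte recognition median turned to -0.18.

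**Figure D2:**
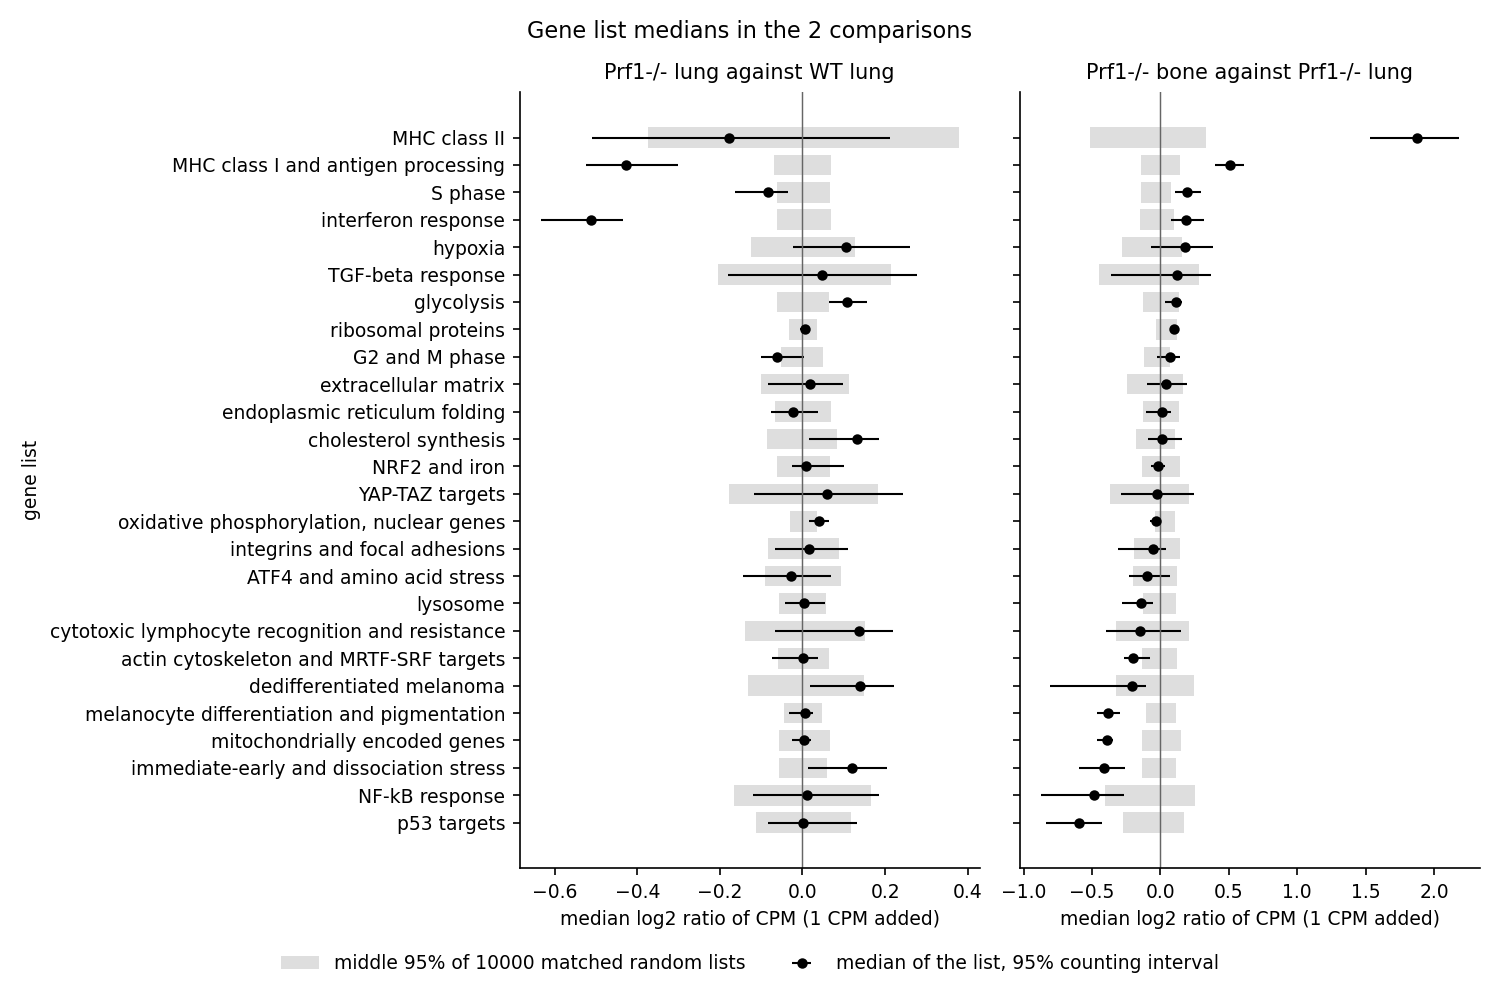
Median log2 ratio of CPM for each gene list with 2 or more measured members in both comparisons, with 95% counting intervals as bars and the middle 95% of 10000 matched random lists in grey; the panels have different horizontal scales. In the lung comparison the interferon and MHC class I medians of -0.51 and -0.43 lie farthest from 0, and in the bone comparison the MHC class II median of 1.88.

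The second comparison, Prf1-/- bone against Prf1-/- lung, asks how melanoma cells differ between metastatic sites in hosts without perforin. Cck, which encodes the peptide hormone cholecystokinin, was 14.98-fold (13.9 to 16.1) higher in bone, at 3270.4 CPM against 218 in Prf1-/- lung and 207 in WT lung. Immunoproteasome and MHC class II genes were also higher in bone: Psmb8 3.44-fold (2.95 to 4.00), Psmb9 3.66-fold (2.85 to 4.71) and H2-Aa, a class II alpha chain gene, 4.39-fold (2.78 to 7.02). The calcium-binding protein genes S100a4 and S100a6 were lower in bone, 9.55-fold (5.12 to 20.1) and 4.08-fold (3.15 to 5.38). Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, was 3.08-fold (2.42 to 3.96) lower. This comparison shares the Prf1-/- lung group with the first, so a chance low value there would lower one ratio and raise the other.

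Cck was uneven among bone cells. Of the 408 bone cells 152 had a Cck UMI (37.3%, 32.5 to 42.1), against 13.1% in WT lung and 11.2% in Prf1-/- lung. Thinned to 1500 UMIs per cell, which left out 1 Prf1-/- lung cell, the shares were 31.1%, 8.96% and 8.28%. In 48 alveolar-like barcodes kept by a looser filter, a type not expected to make Cck, it was 6.25% (1.31 to 17.2) at a median of 566 UMIs. Cells with at least 10 Cck UMIs made up 23.5% (19.5 to 28.0) of bone, 1.78% (1.12 to 2.68) of WT lung and 2.01% (1.34 to 2.90) of Prf1-/- lung, and they held 96.8% of the Cck UMIs in bone.

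**Figure D3:**
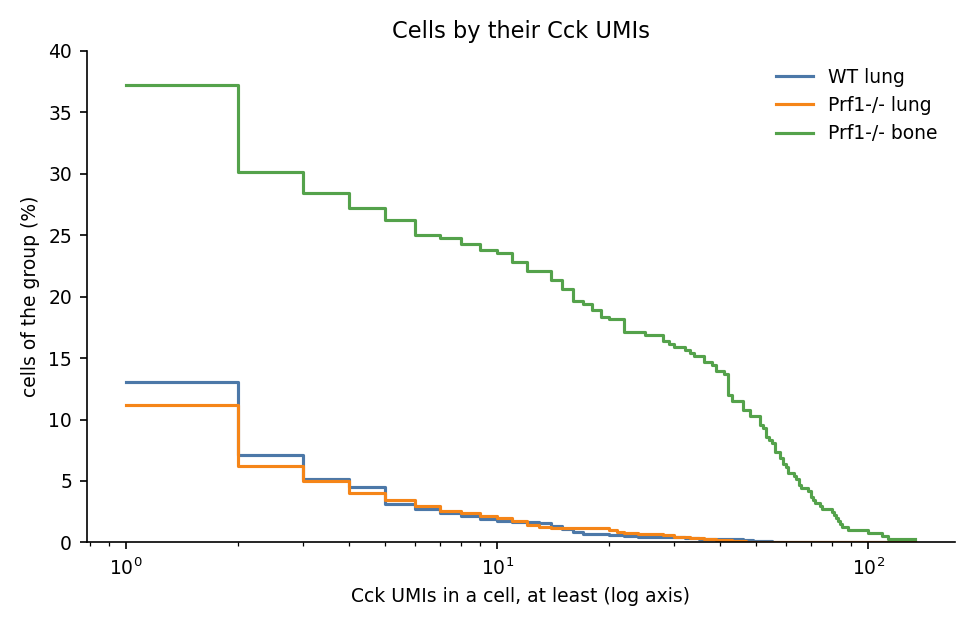
Share of cells (%) in WT lung, Prf1-/- lung and Prf1-/- bone with at least the number of Cck UMIs on the horizontal log axis. At 10 UMIs the shares are 1.78%, 2.01% and 23.5%.

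Other genes named on the higher side were Fosb, an AP-1 transcription factor gene, at 5.72-fold (4.62 to 7.09), the scaffold gene Akap12 at 3.80-fold (2.56 to 5.65) and the class II invariant chain gene Cd74 at 3.48-fold (2.54 to 4.78). Arfgef3 was 3.13-fold (2.49 to 3.93) and the interferon-inducible Mndal 3.12-fold (2.29 to 4.24) higher. Cdca7, a gene of cycling cells, the lysosomal acetyltransferase gene Hgsnat and the monocarboxylate transporter gene Slc16a7 were 3.05, 2.71 and 2.56-fold higher. On the lower side, the chemokine gene Ccl5 was 3.99-fold (3.11 to 5.20), the neuronal tubulin gene Tubb3 4.04-fold (2.64 to 6.47), the amyloid precursor gene App 4.10-fold (2.28 to 8.11) and Emp1 4.06-fold (2.31 to 7.80) lower. The immediate-early genes Egr1 and Atf3 were 3.53 and 2.84-fold lower, Ahnak 3.48-fold, the metabolic coactivator gene Ppargc1a 2.86-fold and Cd109 2.95-fold.

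All 14 measured members of the MHC class I list had ratios above 1 in bone, 5 of them higher by 1.5-fold and none lower, and the median log2 ratio was 0.51 (0.40 to 0.61) at percentile 100. Psmb10 was 1.83-fold (1.57 to 2.13) and the peptide transporter gene Tap1 1.73-fold (1.30 to 2.30) higher. H2-D1 had a ratio of 1.34, Pdia3 1.21, Calr 1.12 and B2m 1.03. Barcodes that passed the cell filter but were not listed in the hashtag matrix had 3411 CPM of the summed MHC class I list. That was below Prf1-/- lung at 3949 and bone at 5043. Whether the listing or calling of barcodes by their hashtag counts shaped this result was not tested. All 4 measured MHC class II genes were higher, with a median of 1.88 (1.53 to 2.18), and H2-Ab1 was 6.097-fold (3.31 to 11.6) higher. Beside these genes, pan-immune markers, almost entirely from 1 member, stood at 304 CPM in bone against 218 in Prf1-/- lung. The monocyte, macrophage and dendritic cell markers stood at 19.0 against 9.84. In WT lung these 2 sums were 273 and 20.0 CPM.

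The interferon response list divided in bone. Its median was 0.19 (0.08 to 0.32) at percentile 99.97, and 8 of 29 measured members were higher and none lower. Gbp4 was 4.88-fold (2.71 to 8.999), the chemokine gene Cxcl9 2.61-fold (1.55 to 4.38), Iigp1 2.35-fold (1.92 to 2.88) and Zbp1 1.83-fold (1.35 to 2.48) higher. Ifitm3, Ifi27, Bst2 and Cxcl10 had ratios of 1.03, 0.994, 1.22 and 0.867.

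The actin cytoskeleton and MRTF-SRF list had a median of -0.20 (-0.27 to -0.08) at percentile 0.270, with 2 of 22 members lower: the actin-binding protein genes Tagln2 at a ratio of 0.565 (0.488 to 0.651) and Cnn2 at 0.629 (0.436 to 0.887). Actb stood at 1.03, Actg1 at 0.857, Myl6 at 0.761 and Cfl1 at 0.842, and Myl9 and Mrtfa had intervals that held 1. The actin median moved to -0.021 among cells thinned to 5000 UMIs and -0.025 in cluster 0. The YAP-TAZ median was -0.03, with Myof, a membrane repair gene, lower at 0.544 (0.379 to 0.765) and Tgfb2 higher at 1.65 (1.05 to 2.56). Asap1, F3, Ptpn14 and Rbms3 passed in neither direction. Of 17 integrin and focal adhesion genes (median -0.05) 3 were lower, among them Itga1 at 0.344 (0.133 to 0.752) and the focal adhesion kinase gene Ptk2 at 0.552 (0.338 to 0.866), while the most abundant, Tln1 and Itgb1, stood at 1.02 and 1.01.

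All 10 measured p53 targets had ratios below 1 in bone, 5 of them lower by 1.5-fold, with a median of -0.60 (-0.84 to -0.43) at percentile 0. Zmat3 had a ratio of 0.414 (0.199 to 0.781) and the apoptosis gene Bax one of 0.7496 (0.677 to 0.829). Of 23 immediate-early and dissociation stress genes 10 were lower and 3 higher, with a median of -0.41 (-0.59 to -0.26). The 3 higher genes included Fosb and Hspa1b, but 1 bone cell held most of the Hspa1b UMIs and its ratio of 6.44 fell to 1.33 without the top cell of each group. Hsp90aa1 and Hspa8, heat shock genes of most cells, stood at 0.999 and 1.01. The NF-kB response list had a median of -0.49, with all 7 members below 0 and 2 lower, one of them Ccl5. Its members Sod2 and Relb stood at 0.726 (0.603 to 0.871) and 0.610 (0.325 to 1.07).

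All 20 measured pigmentation genes had ratios below 1 in bone, with a median of -0.38 (-0.46 to -0.29) at percentile 0. The 4 lower genes included Mlana, a melanosome protein gene, at 0.608 (0.577 to 0.640) and the melanosome transport gene Mlph at 0.612 (0.503 to 0.739). Dct, an enzyme of melanin synthesis, had a ratio of 0.681 (0.656 to 0.706) and Pmel one of 0.911 (0.880 to 0.942). The dedifferentiated melanoma list did not go the other way. Its 5 measured members lay below 0 (median -0.21), among them Vim, an intermediate filament gene, at 0.540 (0.515 to 0.566) and the cadherin gene Cdh2 at 0.524 (0.317 to 0.828), with Zeb2 at 0.908. Of 13 mitochondrially encoded genes 12 lay below 0, with a median of -0.39 at percentile 0, and mt-Nd2 stood at 0.655 (0.610 to 0.703), mt-Atp6 at 0.804 and mt-Nd6 at 0.404 (0.177 to 0.812). The cytotoxic lymphocyte recognition list had a median of -0.15, with 3 of 9 members lower and 1 higher. Cd47, whose product restrains phagocytes, had a ratio of 0.513 (0.378 to 0.684), Pvr, a ligand of lymphocyte receptors, one of 0.466 (0.223 to 0.884) and Mcl1 one of 0.902.

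Among the remaining lists, S phase had a median of 0.20 at percentile 100 (3 of 40 higher), G2 and M phase 0.07, glycolysis 0.11, hypoxia 0.18 and ribosomal proteins 0.10. Medians were -0.03 for nuclear oxidative phosphorylation genes, 0.04 for extracellular matrix, -0.09 for ATF4 and amino acid stress, 0.01 for endoplasmic reticulum folding and 0.01 for cholesterol synthesis. They were 0.12 for TGF-beta response, -0.02 for NRF2 and iron, -0.14 for lysosome and 0.16 for bone metastasis, with the single member Spp1.

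In the cells with at least 2000 genes (98 in Prf1-/- lung and 49 in bone), the interferon median turned to -0.46, Cd74, Cxcl9, Iigp1, Zbp1, Tgfb2 and Hspa1b turned below 0, mt-Nd6 above 0, and the p53 median moved to -0.31, and among cells thinned to 5000 UMIs Gbp4 and Cdca7 also turned below 0. Within clusters 0 and 2 alone, the interferon medians were -0.06 and 0.06, the S phase medians -0.16 and 0.36, the MHC class II medians 1.14 and 2.92, the mitochondrially encoded medians -0.17 and -0.24 and the log2 ratios of Cck 2.24 and -0.89, where cluster 2 leaves out the cluster that Cck leads, and the bone metastasis median turned to -0.61 without cells of 5 or more Cck UMIs.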

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

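The values here come from barcodes of the RNA matrix that are not listed in the hashtag matrix and enter no comparison of the report. The genes were chosen after their values were seen. No explanation was tested for them. Of the 11757 such barcodes 6270 passed the cell filter, with a median of 2418 UMIs, and their summed melanoma markers stood at 13494 CPM, between the levels of the hashtag groups. Unlike the hashtag groups, they were not clustered or named, and doublets of hashtags could not be removed. Cells of other types among them were therefore not set apart. The items named next stood above their level in WT lung, the control group, by more than their counting interval. The exceptions are Psmb8, Ifit3 and the interferon and MHC class I lists. These barcodes come from the same pool of all sources, so WT lung alone is not a like comparator. Cck and Fosb lay within the range of the hashtag groups, so their levels are not an excess over the pool.

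Cck stood at 684 CPM (672 to 697), against 207 in WT lung, 218 in Prf1-/- lung and 3270.4 in Prf1-/- bone, and 282 of the barcodes (4.50%) had 10 or more Cck UMIs. Fosb stood at 64.1 CPM (60.3 to 68.1), against 30.6 in WT lung and 187 in Prf1-/- bone. Isg15, an interferon-induced ubiquitin-like gene, stood at 130 CPM (125 to 136), above all 3 hashtag groups at 81.7, 54.7 and 50.5. The interferon genes did not share this as a set. Ifit3 stood at 105 CPM against 180, 106 and 98.0, and the summed interferon response list at 3662 CPM against 4599, 3554 and 3900. Col1a1, a collagen gene of mesenchymal cells, stood at 15.3 CPM (13.4 to 17.3), above the 0.778, 0.480 and 1.46 of the hashtag groups. The summed fibroblast markers stood at 43.2 CPM (40.1 to 46.5) against 14.3, 11.5 and 18.3, and the osteoblast and marrow stromal markers at 24.1 CPM (21.7 to 26.6) against 4.67, 5.76 and 3.66. Psmb8 went the other way, at 67.1 CPM (63.2 to 71.2), below all 3 hashtag groups. The summed MHC class I list was also below all 3, at 3411 CPM (3383 to 3439) against 4437, 3949 and 5043.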

How the results depend on the processing

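The 4 primary lists in both comparisons, the cells per group and the melanoma-like share gave 171 of 208 values under the alternatives that stayed within the counting interval of the reported one, 34 that moved and 3 that reversed. The lists and genes beside them gave 3153, 406 and 38. TMM and median-of-ratios scaling, the total without mitochondrial and ribosomal protein genes, and both pseudocounts moved no primary list beyond its interval. Using all hashtag singlets changed nothing, since all filtered cells lay in melanoma-like clusters, and removal of 3 Scrublet calls moved no primary list. The stricter filter (119, 98 and 49 cells) and thinning to 5000 UMIs (80, 68 and 36 cells) rest on few cells and account for most reversals. No paired analysis was possible because each condition is 1 hashtag group. Clusters 0 and 2 alone, cells that 3 callers put in the same group and the removal of Cck-rich cells or of cells with other types' transcripts were chosen after seeing the data. Where no cause is given, the cause was not tested.

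Hashtag calling moved sizes. Before the cell filter, the margin rule placed 703, 1593 and 304 barcodes in WT lung, Prf1-/- lung and bone, against 1559, 1789 and 472, and MULTIseqDemux 351 in bone. After the filter the margin rule left 588, 1278 and 267 cells. The looser filter, which keeps small droplets by construction, gave melanoma-like shares of 95.6%, 97.6% and 96.2%.

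In the lung comparison the MHC class I and interferon medians stayed below 0 throughout, but their size depended on the hashtag caller. Both lay farther from 0 under the margin rule and where 3 callers gave the same group. The WT lung barcodes of the margin rule had a median of 1123 hashtag counts before the cell filter, against 747 by HTODemux. Whether the hashtag counts of a cell go with these genes was not tested. MHC class I moved to -0.68 under the margin rule, -0.68 thinned to 5000 UMIs and -0.67 where 3 callers gave the same group. Interferon moved to -0.74 under the margin rule, -0.33 under the stricter filter, -0.43 thinned to 5000 UMIs and -0.65 where 3 callers gave the same group. The actin median moved to -0.10 under the stricter filter and -0.094 thinned to 5000 UMIs, and the YAP-TAZ median to -0.42 thinned to 5000 UMIs and -0.14 in cluster 0.

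In the bone comparison the MHC class I median stayed above 0, at 0.70 by MULTIseqDemux, 0.73 by the margin rule, 0.17 under the stricter filter, 0.32 thinned to 5000 UMIs, 0.39 with no low-value filter, 0.76 where 3 callers gave the same group, 0.37 in cluster 0 and 0.79 in cluster 2. The interferon median reversed to -0.46 under the stricter filter, -0.24 thinned to 5000 UMIs and -0.058 in cluster 0, and moved to 0.40 by the margin rule, 0.37 where 3 callers gave the same group, 0.047 without cells of 5 or more Cck UMIs and 0.063 in cluster 2. The actin median moved to -0.021 thinned to 5000 UMIs and -0.025 in cluster 0, and the YAP-TAZ median to -0.34 under the stricter filter and -0.34 thinned to 5000 UMIs.

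Other reversals in the lung comparison were S phase at 0.10 under the stricter filter, 0.021 thinned to 5000 UMIs and 0.084 in cluster 2. Glycolysis reversed to -0.064 thinned to 5000 UMIs, immediate-early and dissociation stress to -0.051 under the stricter filter and -0.018 in cluster 2, and cholesterol synthesis to -0.0013 under the stricter filter. The bone metastasis list reversed to -0.12 with the total without mitochondrial and ribosomal protein genes and -0.31 with no low-value filter, both of which admit more members than Spp1. Sftpc reversed to 0.47 without the 5 WT lung and 1 Prf1-/- lung cells with 2 or more UMIs of other types' genes, Zbp1 to 0.058 under the stricter filter, Ifit3 to 0.13 under it and 0.11 thinned to 5000 UMIs, and Ccn1 to -0.017, -0.33 and, in cluster 0, -0.17. Without a reversal of a call, Iigp1 moved to -0.070 under the stricter filter and -0.32 thinned to 5000 UMIs, and Ifi47 to -0.58 and -0.24. The cytotoxic lymphocyte recognition median, which held no called gene, turned to -0.094 by the margin rule, -0.18 under the stricter filter, -0.24 and -0.098 thinned to 5000 and 1500 UMIs and -0.071 where 3 callers gave the same group. Other medians near 0 changed sign in such subsets too.

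Other reversals in the bone comparison were S phase at -0.047 thinned to 5000 UMIs and -0.16 in cluster 0 (G2 and M phase moved to -0.34 there and 0.45 in cluster 2), glycolysis at -0.025 in cluster 0 and nuclear oxidative phosphorylation at 0.093 in cluster 2. S100a4 moved from -3.09 to -2.16 under the stricter filter, -2.07 thinned to 5000 UMIs, -2.32 in cluster 0 and -4.47 where 3 callers gave the same group. The bone metastasis median turned to -1.19 under the stricter filter, -0.61 without cells of 5 or more Cck UMIs, -0.45 in cluster 0 and -1.29 in cluster 2. Moves without a reversal included the p53 median, at -0.31 under the stricter filter and -0.36 thinned to 5000 UMIs, and MHC class II, at 4.54 thinned to 5000 UMIs, 1.14 in cluster 0 and 2.92 in cluster 2. The immediate-early and dissociation median moved to -0.099 among members of at least 50 CPM, -0.25 thinned to 5000 UMIs, -0.19 in cluster 0 and -0.72 in cluster 2, and the mitochondrially encoded median to -0.17 in cluster 0 and -0.24 in cluster 2. Cck reversed to -0.89 in cluster 2, which lacks the Cck-led cluster by construction. Its log2 ratio moved to 3.601 by MULTIseqDemux, 4.155 where 3 callers gave the same group and 4.744 under the stricter filter. Under the stricter filter Cd74 reversed to -0.96, Cxcl9 to -2.31, Iigp1 to -1.04, Zbp1 to -1.03, Tgfb2 to -1.20, mt-Nd6 to 1.23 and Hspa1b to -2.26. Thinned to 5000 UMIs Cdca7 reversed to -0.62, Gbp4 to -3.67, Cxcl9 to -2.35, Zbp1 to -4.43, Tgfb2 to -4.22, mt-Nd6 to 2.71 and Hspa1b to -1.98. Hspa1b also reversed by MULTIseqDemux (-0.50), the margin rule (-0.23) and where 3 callers gave the same group (-0.29).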

Other observations

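The tests weighed in this part, the comparison of bone with WT lung and the genes named for Cck-rich cells were chosen after the results had been seen. Set against WT lung directly, bone cells had a median log2 ratio of 0.18 (0.10 to 0.27) for the MHC class I list, 1.32 (0.97 to 1.63) for MHC class II and -0.34 (-0.40 to -0.18) for the interferon response list. The p53 targets had a median of -0.61 (-0.85 to -0.40) and the pigmentation list one of -0.38 (-0.45 to -0.30). Mitochondrially encoded genes had a median of -0.41 (-0.49 to -0.37) and glycolysis genes one of 0.16 (0.12 to 0.25). Most WT lung cells lay in clusters 1 and 2 and most bone cells in clusters 0 and 2.

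Bone cells with 10 or more Cck UMIs (96) differed from those with 0 (256) in more than Cck. The bone cells between, 45 of them with 1 to 4 Cck UMIs, entered neither side. Arfgef3 was 7.57-fold (5.08 to 11.5) higher in the Cck-rich cells, Hgsnat 3.24-fold (2.34 to 4.49) and Spp1 4.15-fold (3.21 to 5.40), while S100a6 stood at 0.0505 (0.00125 to 0.294) and Psmb8 at 0.847 (0.649 to 1.10). The 50 lung cells with 10 or more Cck UMIs also had more Arfgef3, 5.08-fold (3.11 to 7.92), and Spp1, 1.90-fold (1.39 to 2.55), and less S100a6, at 0.387 (0.1997 to 0.679), with Hgsnat at 0.702 (0.226 to 1.66). Whether some of these 50 are bone cells that took up a lung hashtag stays open, since a lung call already bars a high count of the bone hashtag.

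The first pattern weighed is the medians below 0 of the interferon and MHC class I lists in Prf1-/- lung, where 11 of 27 and 4 of 14 members were lower. Cells that held any UMI of 8 genes of lung epithelium and myeloid cells are argued against as the cause. Without them the interferon median was -0.52 and the MHC class I median -0.39, with 1190 of 1239 and 1325 of 1390 cells left. RNA of these types in cells with no UMI of the 8 genes would not be removed this way and stays open. A different mix of the 4 clusters at resolution 0.5 is argued against as the whole cause: the WT lung clusters weighted to the mix of Prf1-/- lung gave medians of only -0.041 for the interferon and -0.011 for the MHC class I list. Within clusters 0, 1 and 2 the medians were -0.53, -0.29 and -0.57 for interferon and -0.42, -0.21 and -0.43 for MHC class I. At resolution 1 a small cluster was led by interferon genes such as Cxcl10 and Rsad2, with 63 of 1239 WT lung and 24 of 1390 Prf1-/- lung cells. Genes of the pattern, such as Iigp1 and Ifit3, are among its leading genes, so these sizes partly restate the difference. A different share of such cells within each cluster at resolution 0.5 stays open. The perforin genotype of the host may contribute, as a hypothesis, and differences between the animals behind each hashtag stay open and untested. The comparison covers only barcodes listed in the hashtag matrix, which held none below 503 counts. Unlisted barcodes that passed the cell filter had 3411 CPM of the MHC class I list, below all 3 hashtag groups. Whether the listing of barcodes shaped the pattern was not tested.

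The second pattern is the Cck-rich cells of bone. Free Cck RNA shared by all droplets is argued against, since 62.7% of bone cells had 0 Cck UMIs where an even spread over their UMIs would leave 0.0295%. Cells of another type are argued against, since the melanoma markers stood at 1.34 times (1.30 to 1.39) their level in bone cells with 0 Cck UMIs. Doublets are argued against, since the median UMI count was 1.00 times that of cells with 0. A Cck-expressing state of melanoma cells that is more frequent in bone is consistent with these values, as a hypothesis, though 1 animal or 1 founding clone could give it too and was not tested.

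The third pattern is the median below 0 of the p53 targets in bone, where 5 of 10 members were lower, with the lower S100a4 and S100a6. A different mix of the 4 clusters at resolution 0.5 is argued against as the whole cause, since the lung clusters weighted to the mix of bone gave a p53 median of -0.17 against the observed -0.60. Within clusters 0 and 2 the p53 medians were -0.52 and -0.55 and S100a6 had log2 ratios of -2.01 and -1.63. Cluster 3, with 88 bone cells against 18, had a p53 median of -0.78. Cluster 1, with 17 bone cells against 548, had a p53 median of 0.06, so the pattern was not seen in every cluster. At resolution 1, a cluster led by S100a6, Ahnak and S100a4 held 136 Prf1-/- lung and 2 bone cells. Another, led by S100a6 and Crip1, held 166 and 12. Genes of the pattern lead these clusters, so their sizes partly restate it. A different share of such cells within the clusters at resolution 0.5 stays open. A stronger dissociation response in the knees, which were digested for longer, cannot be told apart from an effect of the site: the immediate-early and dissociation list had a median of -0.41 in bone, but members went both ways and the median was -0.099 among those of at least 50 CPM. The metastatic site stays open as well and was not tested.

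The interferon list that divided in bone was also read by arm, with both arms chosen after its genes had been seen, so the values describe the division and test nothing. Over 9 measured gamma-arm genes, such as Gbp4, Cxcl9 and Iigp1, the median log2 ratio of bone to Prf1-/- lung was 0.83 (0.55 to 1.03), and over 11 type I genes, such as Ifit3 and Isg15, it was 0.00 (-0.14 to 0.16). Against WT lung the gamma arm stood at 0.12 (-0.15 to 0.28) and the type I arm at -0.51 (-0.72 to -0.28), so there the gap came from lower type I genes. Between the lung groups both arms were lower in Prf1-/- lung, at -0.71 and -0.44. The gamma-arm examples reversed in small subsets of cells, Cxcl9 to -2.31 and Iigp1 to -1.04 under the stricter filter and Gbp4 to -3.67 thinned to 5000 UMIs. Both interferon types induce many of the same genes, and no measurement of interferon itself was used here.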
